A study of Mus musculus with 4 samples.

How the data were processed

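Omni-ATAC-seq libraries from cultured mouse bone marrow cells were analysed, 1 library each of WT CMP/GMP, Cxcr3-/- CMP/GMP, WT monocytes and Cxcr3-/- monocytes, grouped by their labels. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to mm10 with Bowtie2 and handled with SAMtools; the peak caller is not given in the sources used here. The deposited files list accessible intervals per sample, called by the authors, and whether the duplicate sequencing that the labels mention was pooled before calling is not stated. The deposited score of each interval equals the whole part of 10 times its −log10 q, as read from the values of the authors' files, and was not used further. The deposited fold enrichment is the ratio, computed by the authors' peak caller, of the tag pileup at the summit to its expected background. The deposited −log10 p and −log10 q values were computed by the authors' caller for the summit of each interval. These are each interval's own values, and they served only to describe, rank and filter within a list.

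Intervals with the same chromosome, start and end were counted once, and chromosomes 1 to 19, X and Y were kept. For presence comparisons each list was reduced to its 69521 best intervals by q, the length of the shortest list, because the lists differ in length. A library-only interval was one of the 10000 best of a library that shared no base with any of the 69521 of the other. Shares carry exact 95% Clopper-Pearson intervals, and a count of 0 was taken to allow up to 3. The comparisons were Cxcr3-/- against WT in each cell type and monocytes against CMP/GMP in each genotype, and the 15 presence patterns over the 4 libraries were counted on merged regions. The comparisons, the other settings tried unless named below as added, the 21 gene lists and the rule for named genes were chosen before the data were examined.

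The pileup ratios were added after the data had been seen and are secondary to the presence comparisons. The deposited fold and −log10 p of the authors together determine the whole-number tag pileup at a summit if the caller used a Poisson background and 1 added tag, and a whole number within a tolerance of 0.001 was found for all but 2, 39, 3 and 2 intervals of WT CMP/GMP, Cxcr3-/- CMP/GMP, WT monocytes and Cxcr3-/- monocytes. The background gave 135, 194, 95.6 and 97.2 tags per 10 kb in the same order, the measure of depth used here. Overlapping intervals of the 4 lists were merged into regions, with the highest pileup per library. Pileups were divided by factors of 0.791, 1.29, 1.11 and 0.879, from the median over the 44552 regions called in all 4 libraries. Ratios were taken only for regions called in both libraries with a mean pileup of at least 30 tags. Calls for the ratios came from the full lists, while library-only status was judged against the equal-length lists. A library-only interval can therefore overlap a weaker call of the other library and have a ratio, as in Mapk4 in WT and near Sik1 in Cxcr3-/-. Each log2 ratio has an exact 95% interval for counting error, and a gene's value is the mean over regions in its body plus 10 kb on either side. At the median pileups of 21 to 29 tags a single region is measured coarsely, with simulated counting error, drawn from Poisson counts with the same mean in both libraries, giving an SD near 0.3 at the regions used.

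Of 526 listed symbols, 6 had no match (Cxcl11, Rigi, Mx1, Mx2, Ahsp and Tpsab1), and 4 were second names of genes also listed, leaving 516 genes among 21883 protein-coding genes of GRCm38.p6. The lists were the CXCR3 axis, stem and progenitor, granulocyte and GMP granule, monocyte, macrophage, dendritic cell, interferon response, inflammatory and NF-kB, chemokine and receptor, angiogenesis, immune checkpoint and suppression, antigen presentation, proliferation, B cell, T and NK cell, erythroid, megakaryocyte, mast, basophil and eosinophil, stromal and endothelial, hepatocyte, and housekeeping genes. Some genes, such as Kit and Mmp9, are on more than 1 list. A list's number of intervals in its loci, and its median log2 ratio minus that of all genes, were placed among 10000 random lists of the same size, matched on the number of locus intervals or on pileup and number of regions. These percentiles describe the libraries and are not p-values. Lists with fewer than 5 genes with a ratio, which was the case for the CXCR3 axis, have no signal value.

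Genes were named by rule: for each comparison and direction the 10 genes with the most library-only intervals, up to 4 members per list with a library-only interval in their locus, the 3 best-ranked library-only intervals, and Cxcr3. The 10 regions with the largest ratios per direction were added after the data had been seen, as were the list members given with values, which were chosen mostly for the largest values. Planned promoters were replaced by gene ends, 1 kb around either annotated end, and the nearest TSS by the nearest gene body within 100 kb, because the gene table has no strand. Exons and introns were not told apart, and motifs were not analysed because they need a genome sequence, which was not used here.

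The other settings tried were all deposited intervals, a reciprocal overlap of 50%, summits within 250 bp, a −log10 q of at least 5, ranking by fold enrichment, autosomes alone, the 5000 or 20000 best, intervals under 2000 bp, loci with 50 kb on either side, gene ends of 2.5 kb and 2 Mb windows. Scaling by background tags, a mean pileup of at least 60 tags and random lists matched on gene density were added later. The steps were tested on simulated data: pileups were recovered exactly in 100% of intervals, 300 of 300 planted library-only intervals were found in each comparison with 0 in the wrong direction, and counting intervals covered 95.9 to 96.0% of true ratios. The pileups were simulated with the same formula that was inverted, and the planted intervals were removed from a copy of the same list. Both check the steps as written, and not the caller's formula or the comparison of separate libraries. Of 400 random lists, 4.5% lay outside the central 95%, and all of 50 shifted lists did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.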

Results

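Chromatin accessibility was measured by Omni-ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in cultured mouse bone marrow cells of the C57BL/6J strain. There were 4 libraries, 1 each from wild-type (WT) and Cxcr3-/- common myeloid and granulocyte-monocyte progenitors (CMP/GMP) and from WT and Cxcr3-/- monocytes. Cxcr3 encodes a chemokine receptor for Cxcl9 and Cxcl10, and the study concerns macrophages that carry it in liver cancer. The labels list hepatocellular carcinoma as the disease state, while the design text places these cells in culture. Each library came with its own list of called accessible intervals, 69521 in WT CMP/GMP, 80171 in Cxcr3-/- CMP/GMP, 98257 in WT monocytes and 78244 in Cxcr3-/- monocytes. These lists covered 19.5, 26.4, 28.1 and 23.3 Mb, with median widths of 224, 256, 220 and 237 bp. The median number of tags stacked at a summit (the summit pileup) was 29 in Cxcr3-/- CMP/GMP and 21 in each of the other 3 libraries. Background tag density was 135 and 194 tags per 10 kb in WT and Cxcr3-/- CMP/GMP and 95.6 and 97.2 in WT and Cxcr3-/- monocytes. With 1 library per group no difference has a replicate check, so no p-values are given. The intervals printed cover counting error only, apart from those of the gene density trend, which come from resampled windows.

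Cxcr3 itself lies on the X chromosome from 101731535 to 101734147 (mm10). An accessible region over one end of the gene, from 101733698 to 101734465, was called in all 4 libraries. Its summit pileup was 34 tags in WT CMP/GMP, 84 in Cxcr3-/- CMP/GMP, 41 in WT monocytes and 23 in Cxcr3-/- monocytes. After scaling, the Cxcr3-/- to WT log2 ratio there was 0.60 (95% counting interval 0.01 to 1.22) in CMP/GMP and −0.49 (−1.30 to 0.28) in monocytes. The monocyte to CMP/GMP log2 ratio was −0.22 (−0.91 to 0.48) in WT and −1.32 (−2.05 to −0.64) in Cxcr3-/-. These values depend on the scaling: by background tags, the genotype ratios were 0.78 (0.19 to 1.40) and −0.86 (−1.66 to −0.09), and the cell-type ratios 0.76 (0.07 to 1.46), of opposite sign, and −0.87 (−1.61 to −0.19). A second region beside Cxcr3, from 101730082 to 101730329, was called in both monocyte libraries, with 52 tags in WT and 28 in Cxcr3-/- (log2 ratio −0.55, −1.27 to 0.14, or −0.92, −1.64 to −0.23, by background tags), and in neither CMP/GMP library. Inside the gene, a weaker interval starting at 101733312 in WT monocytes (16 tags) and at 101733314 in Cxcr3-/- CMP/GMP (25 tags) was called in those 2 libraries. Cxcr3-/- monocytes had one more weak interval at 101740853 to 101740963 (9 tags). The deleted part of Cxcr3 is not given in the sources used here, and an accessible gene end outside a deleted part checks nothing about the genotype. Over the 5 matched genes of the CXCR3 axis list, which holds the receptor, its ligands and Dpp4, the loci held 17 and 17 intervals in WT and Cxcr3-/- CMP/GMP and 14 and 15 in WT and Cxcr3-/- monocytes.

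**Figure D1:**
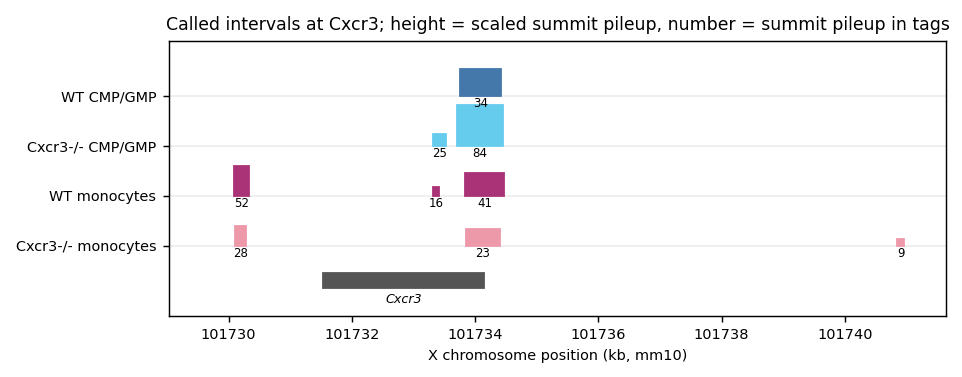
Called intervals at Cxcr3 along the X chromosome (position in kb, mm10), 1 row per library; box height is the scaled summit pileup and the printed number is the recovered pileup in tags. The gene-end interval appears in all 4 libraries with 34, 84, 41 and 23 tags, and the interval starting at 101730082 in WT monocytes in both monocyte libraries with 52 and 28 tags.

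The first comparison asked whether loss of Cxcr3 alters accessibility in CMP/GMP. None of the 10000 best Cxcr3-/- intervals was missing from the WT list and none of the 10000 best WT intervals was missing from the Cxcr3-/- list, each 0 of 10000, where 1 shared base makes a partner. By counting error within this library pair alone, that allows a share of up to 0.03% (exact 95% limit 0.037%). A region with less signal keeps its partner as long as it is called, so the 0 covers only loss of a call. With a reciprocal overlap of 50% the counts were 460 and 498, and with summits within 250 bp 111 and 159. Over the 69521 best intervals of each library, 83.0% (95% Clopper-Pearson interval 82.7 to 83.3%) of the Cxcr3-/- intervals and 86.7% (86.4 to 86.9%) of the WT intervals were shared. The best-ranked interval without a partner stood at rank 18454 in Cxcr3-/- and 23298 in WT CMP/GMP. In Cxcr3-/- it was an interval in App, the amyloid precursor protein gene (chromosome 16, 85148629 to 85148969, 59 tags), followed by one 22374 bp from Lrrc32 (chromosome 7, 98524099 to 98524298, 55 tags, rank 19081) and one in Nr4a3 (chromosome 4, 48045007 to 48045245, 93 tags, rank 20124). In WT the first were an interval with no protein-coding gene within 100 kb (chromosome 10, 15757624 to 15757782) and intervals in Zfc3h1 and Robo2, each with 23 tags. These intervals lie outside the rule for named genes and were chosen after their values were seen.

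The regions called in both CMP/GMP libraries differed little in signal. Among 29415 regions with a mean pileup of at least 30 tags, the log2 ratio had an SD of 0.303, against 0.302 for simulated counting error alone. There were 41 regions more than 2-fold higher in Cxcr3-/- and 40 more than 2-fold higher in WT, where counting error alone gave 64 and 28. Fewer regions passed 2-fold toward Cxcr3-/- than in the simulation, and the ratio also varied with gene density, as given below, so the simulated error is an approximate scale and the equal SD does not exclude small differences. The largest ratios toward Cxcr3-/- near a gene lay 27387 bp from Wdr5 (chromosome 2, 27563785 to 27564092, log2 ratio 1.25, 0.47 to 2.11, 66 against 17 tags), 61660 bp from Eed (1.20, 0.35 to 2.12) and in Dnm2 (1.16, 0.41 to 1.97). The regions named in this paragraph are the extremes of 29415 ratios. Simulated counting error alone gave larger ratios than these in both directions, so an interval that leaves out 0 does not set a region apart. Further regions above 1.1 were near Armc12, Depdc7, Bco2 and Dixdc1. The largest ratios toward WT near a gene were in Nxpe3 (chromosome 16, 55858560 to 55858829, −1.47, −2.28 to −0.69, 23 tags in Cxcr3-/- against 39 in WT), in Cpq (−1.33, −2.13 to −0.55), 195 bp from Plxna2 (−1.29, −2.03 to −0.57) and near Tmem252 (−1.25), Kcnv2 (−1.24), Adck1 (−1.19), Plcb4 (−1.16), Zfp945 (−1.16) and Alg13 (−1.13). At a mean pileup of at least 60 tags, none of 11250 regions passed 2-fold in either direction. Scaling by background tags instead shifted all ratios by 0.18 and gave 170 and 6 regions.

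Among the fixed gene lists, the granulocyte and GMP granule list stood apart in CMP/GMP. Of its 22 genes with a ratio, 19 lay above 0, and the list median lay 0.21 log2 units above that of all genes, higher than all 10000 random lists of matched genes. Its members include the matrix protease gene Mmp9 (0.65 ± 0.70, the 95% counting error), the calprotectin gene S100a9 (0.62 ± 0.66), the transcription factor gene Gfi1 (0.49 ± 0.45), and the granule protease genes Elane and Prtn3, which share regions and so share 1 value (0.39 ± 0.33). Ctsg (−0.16 ± 0.25), Mpo (−0.09 ± 0.25) and Chil3 (−0.01 ± 0.40), also granulocyte genes, did not share the direction. They lay below the median of all genes (0.07), though within their counting error of it. Background scaling puts them above 0 but shifts all genes alike, so they stay below that median. The loci of this list held 103 intervals in Cxcr3-/- and 101 in WT CMP/GMP, which lay at percentile 65.6 of random lists, so the difference was in signal and not in the number of intervals. By number of intervals, the chemokine and receptor list held 119 in Cxcr3-/- and 104 in WT (percentile 99.4) and the megakaryocyte list 94 and 81 (percentile 98.9). With all deposited intervals in place of equal-length lists, the chemokine list lay inside the central 95% of random lists. The list medians relative to all genes lay between −0.11 for hepatocyte markers and 0.08 for housekeeping genes in the other 19 lists with at least 5 measured genes. Among them were monocyte (0.03), macrophage (−0.04), dendritic cell (−0.02), stem and progenitor (−0.01), interferon response (−0.03), inflammatory and NF-kB (0.01), and proliferation genes (0.00), all within the central 95% of random lists.

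The second comparison set Cxcr3-/- against WT monocytes. Again none of the 10000 best intervals of either library lacked a partner in the other, 0 of 10000 in each direction, where 1 shared base makes a partner. With a reciprocal overlap of 50% there were 158 in Cxcr3-/- and 159 in WT, and with summits within 250 bp 110 and 115. Of the 69521 best intervals, 86.9% (86.7 to 87.2%) of the Cxcr3-/- and 85.7% (85.4 to 86.0%) of the WT intervals were shared. The best-ranked WT interval without a partner stood at rank 22346, 1412 bp from the translation elongation factor gene Eef2 (chromosome 10, 81175076 to 81175276, 48 tags). Other intervals without a partner were in Lrrc72 (31 tags) and Cry1 (25 tags) in Cxcr3-/- and near Grap (31 tags) in WT, all chosen after their values were seen.

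The signal at shared regions varied more between the monocyte libraries than counting error gives. Over 30649 regions the SD of the log2 ratio was 0.358, against 0.294 for counting error alone. There were 81 regions more than 2-fold higher in Cxcr3-/- and 123 more than 2-fold higher in WT, where counting error alone gave 23 and 52. Toward Cxcr3-/- the largest ratio near a gene lay in Dpys, a pyrimidine-degrading enzyme gene (chromosome 15, 39785324 to 39785901, 1.90, 1.08 to 2.78, 50 against 17 tags). Next among regions near a gene came those near Dyrk2 (1.37, 0.59 to 2.20) and Crbn (1.37, 0.59 to 2.20), in Peli2 (1.34, 0.65 to 2.06), at one end of Olfr111 (1.31, 0.79 to 1.84, 94 against 48 tags), and in Tafa2 (1.29), Slc16a7 (1.27) and the integrin gene Itgb8 (1.27). Toward WT the largest were near Eef2 (−1.54, −2.55 to −0.64, 13 against 48 tags), in Arhgap23 (−1.51, −2.52 to −0.60), near Usp3 (−1.44), in Niban2 (−1.42, −2.22 to −0.69, 20 against 68 tags) and in the focal adhesion gene Pxn (−1.40). Aunip (−1.37), Micall2 (−1.33), Ddx19b (−1.31), Atad5 (−1.31) and Tifab (−1.30) followed. The regions named in this paragraph are the extremes of 30649 ratios. Simulated counting error alone also reached ratios between −1.6 and −1.5 and between 1.4 and 1.5. Apart from Dpys, an interval that leaves out 0 therefore does not set a named region apart. The monocyte ratio also varied with gene density, more strongly than in CMP/GMP, as given below, and its spread includes that trend. At a mean pileup of at least 60 tags, 7 regions were more than 2-fold higher in Cxcr3-/- and 8 in WT, of 11598. Background scaling shifted all ratios by −0.37 and gave 3 and 1255, so the balance between the directions depends on the scaling.

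Antigen presentation genes carried less signal in Cxcr3-/- than in WT monocytes, relative to all genes. Of 23 with a ratio, 21 lay below 0, and the list median lay −0.26 log2 units from that of all genes, at percentile 0.15 of matched random lists. Neighbouring genes of the list that share regions count as separate genes here, and the random lists were not matched on position. How many of the 21 share regions was not counted. Examples are the class II genes H2-Oa (−1.06 ± 0.71) and H2-Ab1 (−0.74 ± 0.53) and the peptide-loading gene Tapbp (−0.58 ± 0.26), while Ciita, the class II transactivator gene, stood at 0.37 ± 0.57. The loci of the list held 105 intervals in Cxcr3-/- and 119 in WT (percentile 2.24). When random lists were matched on gene density instead, the signal percentile was 14.7, and with all deposited intervals the difference in interval number lay inside the central 95% of random lists. Angiogenesis genes had a median 0.13 above all genes (percentile 98.6, or 93.0 with lists matched on gene density), with Ccn1 at 0.81 ± 0.62 and Vegfc at 0.69 ± 0.62 but Vegfa at −0.87 ± 0.72. Stem and progenitor genes had a median 0.13 above all genes (percentile 97.9, or 44.4 matched on gene density), with Adgrl4 at 0.58 ± 0.28 and Cd34 at 0.57 ± 0.28. The granulocyte loci held 65 intervals in Cxcr3-/- and 77 in WT (percentile 1.41; inside the central 95% with all deposited intervals), while their signal lay −0.06 from all genes. The monocyte (−0.08), macrophage (−0.07), chemokine and receptor (−0.05), interferon response (−0.01), inflammatory (−0.07), immune checkpoint (−0.05) and housekeeping (−0.07) lists lay within the central 95% of random lists. Over both genotype comparisons, 4 of 42 list values by interval number and 4 of 40 by signal lay outside that range, where 2.1 and 2.0 would be outside by chance.

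The Cxcr3-/- to WT ratio moved with gene density, in opposite directions in the 2 cell types. Across regions, which are not independent replicates, Spearman's rho between the ratio and the number of protein-coding genes in the 1 Mb window around the region was 0.175 in CMP/GMP and −0.391 in monocytes. The median log2 ratio went from −0.05 in the regions with the fewest genes around them to 0.12 in those with the most in CMP/GMP, and from 0.22 to −0.23 in monocytes.

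**Figure D2:**
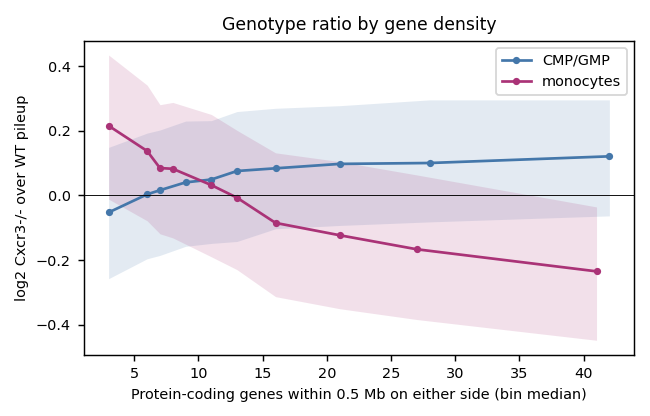
Median log2 Cxcr3-/- over WT summit pileup ratio (y axis) by the number of protein-coding genes in the 1 Mb window around a region (x axis, bin medians), with bands from the lower to the upper quartile. Medians run from −0.05 to 0.12 in CMP/GMP and from 0.22 to −0.23 in monocytes.

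The third comparison set monocytes against CMP/GMP in WT, and here strong regions differed. Of the 10000 best WT monocyte intervals, 748 (7.48%, 6.97 to 8.01%) had no partner in WT CMP/GMP, and 197 (1.97%, 1.71 to 2.26%) of the 10000 best WT CMP/GMP intervals had none in monocytes. Monocyte-only intervals clustered around Maf, a transcription factor gene of macrophages, with 4 intervals, the best 52805 bp away (chromosome 8, 115650169 to 115650715, 118 tags). Camk2d, Nedd4l, Dner and Cped1 had 3 each, and Clec16a, Anxa5, App, Fmo4 and Mtap 2 each. The best-ranked was an interval in the kinase gene Camk2d (chromosome 3, 126831397 to 126831963, rank 104, 235 tags), where equal accessibility would give 167 tags in the CMP/GMP library. The next 2 lay more than 100 kb from any protein-coding gene, on chromosome 13 from 107485605 to 107486009 (152 tags) and on chromosome 11 from 113063092 to 113063772 (192 tags). CMP/GMP-only intervals were led by Erich1 (chromosome 8, 14072624 to 14072902, rank 1116, 83 tags), Tax1bp3 (chromosome 11, 73176892 to 73177338, 112 tags) and Mapk4 (chromosome 18, 73948778 to 73949462, 112 tags). Kctd1, Cdh17, Dym, Nrxn3 and Unc5c had 2 CMP/GMP-only intervals each, and Ppa2 and the cell cycle inhibitor gene Cdkn2b 1 each.

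Members of the fixed lists with a monocyte-only interval in WT included the lysosomal protease gene Lgmn (chromosome 12, 102426345 to 102426702, 114 tags) and the receptor gene Trem2 (chromosome 17, 48355735 to 48356449, 122 tags, an interval shared with its neighbour Treml1) of the macrophage list. Others were Klf4 of the monocyte list (63 tags), Lmo2 (81 tags) and Runx1 (91 tags) of the stem list, Tcf4, Oas2 and Oas3 (1 shared interval), Ackr3, Plaur, Lgals3 (117 tags), Il4ra, Itgb3 (97 tags) and Il1rl1 (90 tags). Members with a CMP/GMP-only interval included Gpnmb (47 tags) and the pre-B-cell receptor genes Vpreb1 and Igll1 through 1 shared interval (58 tags). Only 2.67% (1.64 to 4.10%) of monocyte-only and 6.09% (3.19 to 10.4%) of CMP/GMP-only intervals lay at gene ends, against 45.5% and 50.6% of the shared intervals among the 10000 best.

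By signal at shared regions, WT monocytes and CMP/GMP differed far beyond counting error, with an SD of 0.784 against 0.300 over 25518 regions, 2767 regions more than 2-fold higher in monocytes and 1700 more than 2-fold higher in CMP/GMP. The highest monocyte ratios were in Frmd4a (3.50, 2.53 to 4.65, 143 against 9 tags), near the Notch pathway gene Rbpj (3.40, 2.49 to 4.49), in Cdk18 (3.29) and N4bp2l2 (3.12), and near Tmem230 (3.12), Atp6v1g3 (3.08) and Larp4b (3.04). Megf11 (3.02), Abca9 and Itprid2 completed the 10 highest. The highest CMP/GMP ratios near a gene were in Mapk4 (−4.49, −5.84 to −3.40, 7 against 112 tags), near Gm42427 (−4.40) and Adgrg3 (−4.33), in Kcnh7 (−3.78), and at or near Abca13 (−3.66), Plet1 (−3.64), Epha7 (−3.58) and 3110082I17Rik (−3.58). A region 74157 bp from Kit, the stem cell factor receptor gene (chromosome 5, 75730592 to 75731243), had a ratio of −3.56 (−4.61 to −2.65, 11 against 92 tags). Background scaling shifted these ratios by 0.99 and gave 13109 and 265 regions beyond 2-fold, so list values are given relative to all genes.

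Relative to all genes, macrophage and chemokine genes carried more signal in WT monocytes than in CMP/GMP, and progenitor and granule genes less. With background scaling the medians of the stem and granule lists themselves lay above 0, at 0.53 and 0.67. The macrophage list had a median 0.52 above all genes, higher than all 10000 random lists, with the complement genes C1qa, C1qb and C1qc at 2.17 ± 0.62 through shared regions and the efferocytosis receptor gene Mertk at 1.17 ± 0.54. Its loci held 210 intervals in monocytes and 157 in CMP/GMP (25 genes with more, 2 with fewer). Chemokine and receptor genes lay 0.65 above all genes, with Cxcr6 at 1.40 ± 0.70 and Ccl17 at 1.18 ± 0.52, and monocyte genes 0.32 above (percentile 98.9), with S100a4 at 1.00 ± 0.34, Klf4 at 0.73 ± 0.41 and the growth factor receptor gene Csf1r at 0.63 ± 0.34. The monocyte loci held 151 and 119 intervals. Stem and progenitor genes lay −0.45 from all genes (percentile 0.005), with Kit at −1.85 ± 0.54 and Sox4 at −1.24 ± 0.36, and their loci held 204 and 254 intervals. Granulocyte and GMP granule genes lay −0.30 from all genes (percentile 2.34), with Chil3 at −2.69 ± 0.90, Ctsg at −1.74 ± 0.42, Fcnb at −1.31 ± 0.55 and the myeloperoxidase gene Mpo at −1.09 ± 0.48, while Mmp9 stood at 1.02 ± 0.51. The stem, granulocyte, B cell and T and NK cell lists had fewer intervals in monocytes than in CMP/GMP on equal-length lists and more on the full lists, which differ in length.

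Markers of other cell types moved as well. B cell genes had a median −0.65 from all genes (percentile 0.05), with Cr2 at −1.84 ± 0.48, but 4 of 11 lay above 0, among them Dntt at 1.75 ± 0.80. B cell loci held 45 intervals in monocytes and 61 in CMP/GMP (percentile 1.39), T and NK cell loci 67 and 85 (1.79), and erythroid loci 33 and 48 (0.90). With 50 kb around genes, T and NK cell loci held 199 and 202 (percentile 43.6), inside the central 95%. By signal, the T and NK cell (−0.04), erythroid (−0.02), megakaryocyte (−0.07), hepatocyte (−0.14) and housekeeping (−0.10) lists lay within the central 95% of random lists. So did the mast, basophil and eosinophil list, whose median was 0.29 above all genes while its mean was negative, with Prg2 at −2.49 ± 0.84. Stromal and endothelial genes lay 0.48 above all genes (percentile 98.4), over 7 genes. Immune checkpoint and suppression genes lay 0.26 above (percentile 96.4, or 98.0 matched on gene density), with Nos2 at 1.36 ± 0.60, Cd40 at 1.25 ± 0.72 and Arg1 at 1.23 ± 0.47. Dendritic cell (0.12), interferon response (−0.06), inflammatory (0.02), angiogenesis (0.16), antigen presentation (0.14) and proliferation genes (0.01) lay within the central 95%.

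The fourth comparison set monocytes against CMP/GMP in Cxcr3-/-, with numbers of library-only intervals similar to those in WT. Some list medians relative to all genes were close to WT, such as macrophage (0.53, WT 0.52). Others were not, such as antigen presentation (−0.31, WT 0.14), B cell (−0.05, WT −0.65) and dendritic cell genes (0.51, WT 0.12). List means, not taken relative to all genes, also differed for antigen presentation (−0.32, WT 0.12). They were close for B cell genes (−0.19, WT −0.12) and lower than in WT for dendritic cell genes (0.06, WT 0.24). The contrasts of the B cell and dendritic cell medians were thus not seen in their means. At regions called in all 4 libraries such shifts of list medians restate the genotype ratios, since the same libraries are used. Monocyte-only intervals numbered 759 (7.59%, 7.08 to 8.13%) and CMP/GMP-only intervals 137 (1.37%). Camk2d had 4 monocyte-only intervals, the best again first in rank (chromosome 3, 126831386 to 126831953, rank 194, 209 tags), and Maf, Macf1, Tnrc6a, Magi2, Zbtb20 and Vps13d 3 each. Mical2, Slc39a10 and Mtap had 2 each. The next best regions were 37923 bp from Socs6 (chromosome 18, 88932099 to 88932523, 151 tags) and on chromosome 13 from 110929598 to 110929967 (136 tags), with no protein-coding gene within 100 kb. The CMP/GMP-only regions were led by one on chromosome 17 from 83990412 to 83990978 (188 tags), also without a gene within 100 kb, one 57197 bp from Kctd1 (157 tags), and the region near Kit (chromosome 5, 75730592 to 75731243, 153 tags). Kctd1 and Igf1r had 2 CMP/GMP-only intervals each, and Sik1, Gm42427, Aff3, P2rx3, Erich1, Fads2 and Igll1 1 each. List members with a monocyte-only interval were Mecom, Klf4 (59 tags), Lgmn (74 tags), Trem2 with Treml1 (79 tags), Msr1, Naaa, Lgals3, Vtcn1, Tnfsf4, Il7r, Itgb3, Il1rl1, Cd200r3 and Gusb. Those with a CMP/GMP-only interval included Itgb2l, Vpreb1 with Igll1 (116 tags) and Cd200r3.

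Shared regions in Cxcr3-/- had an SD of 0.855 against 0.298 for counting error over 29508 regions, with 3232 more than 2-fold higher in monocytes and 2885 in CMP/GMP, or 6040 and 1144 with background scaling, a shift of 0.44. The highest monocyte ratios near a gene were near Tmem37 (4.30, 3.42 to 5.34, 148 against 11 tags), in Ndst3 (3.98), near Hells (3.95) and Katnal2 (3.91), in Frmd4a (3.76), near Rapgef5 (3.73), and in the cathepsin gene Ctsh (3.66) and Nav2 (3.52). The highest CMP/GMP ratios near a gene were in Mapk4 (−3.71, −4.79 to −2.80, 10 against 192 tags), Tbc1d14 (−3.50), near Ikzf2 (−3.46), in 3110082I17Rik (−3.35), at Mei4 (−3.32) and Bcr (−3.30), and at or near Man1a (−3.19), Sik1 (−3.18), Ptprm (−3.12) and Sash1 (−3.08). Granulocyte and GMP granule genes lay −0.70 from all genes, lower than all 10000 random lists, with Chil3 at −1.78 ± 0.62, Ctsg at −1.66 ± 0.39 and Gfi1 at −1.01 ± 0.53, and their loci held 65 intervals in monocytes and 103 in CMP/GMP. Macrophage genes lay 0.53 above all genes, higher than all random lists, with C1qa, C1qb and C1qc at 2.12 ± 0.54, Mmp12 at 1.51 ± 0.45 and the scavenger receptor gene Cd36 at 1.39 ± 0.25, and their loci held 208 and 159 intervals. Stem and progenitor genes lay −0.20 from all genes (percentile 1.73), with Kit at −2.16 ± 0.62 and 210 intervals against 251. Chemokine genes lay 0.42 above (percentile 99.9), dendritic cell genes 0.51 (99.7) and angiogenesis genes 0.45 (percentile 99.99), the last with the angiopoietin receptor gene Tek at 2.26 ± 0.83 but Vegfa at −1.13 ± 0.53. Of the 15 dendritic cell genes, 8 lay above 0 and 7 below. Antigen presentation genes lay −0.31 from all genes (percentile 0.70, or 6.64 matched on gene density), with H2-Oa at −1.01 ± 0.70 but Ciita at 2.47 ± 0.88. Monocyte genes lay 0.27 above (percentile 96.7), with 157 intervals against 129 (percentile 99.3), and T and NK cell loci held 65 and 86 intervals (percentile 0.69). With 50 kb around genes, T and NK cell loci held 202 and 216 (percentile 29.5), inside the central 95%. The B cell (−0.05), stromal (0.40), megakaryocyte (0.26), erythroid (−0.30), mast (−0.15), hepatocyte (0.16) and housekeeping (−0.18) lists lay within the central 95% by signal. Over the 4 comparisons, 16 of 84 list values by interval number and 18 of 80 by signal lay outside that range, where 4.2 and 4.0 would be outside by chance.

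**Figure D3:**
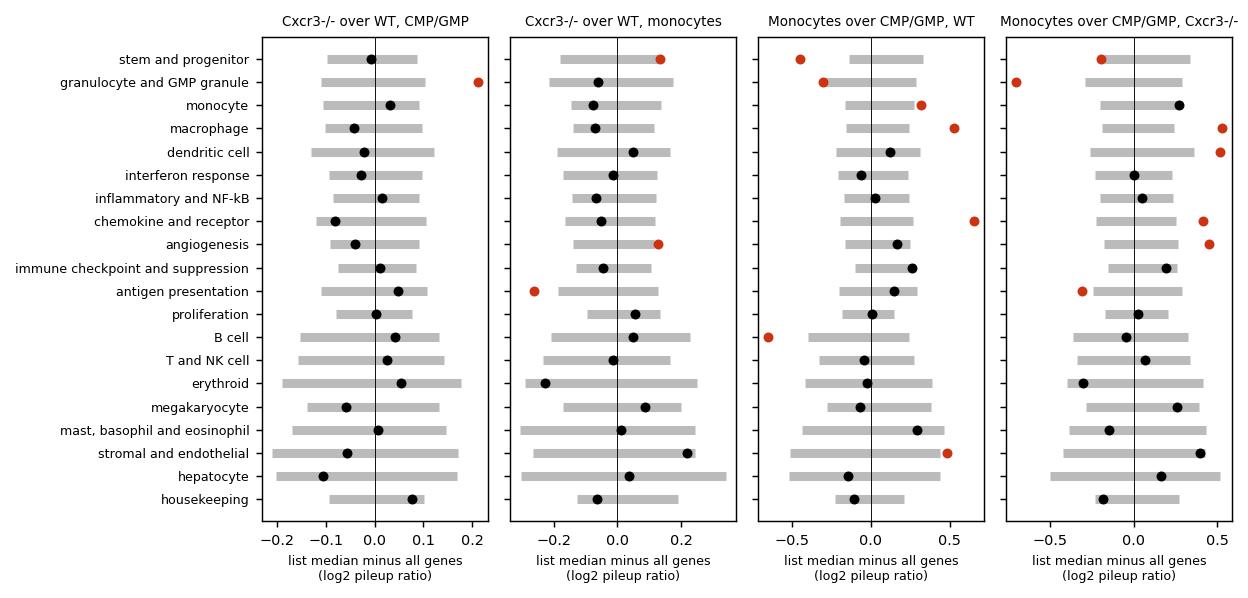
Median log2 summit pileup ratio of each fixed gene list minus that of all genes (x axis), 1 panel per comparison; grey bars span the central 95% of 10000 random matched lists and red points lie outside it. The granulocyte list lies at 0.21 for Cxcr3-/- over WT CMP/GMP and at −0.70 for monocytes over CMP/GMP in Cxcr3-/-, and the macrophage list at 0.52 and 0.53 in both cell-type panels.

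Across the 4 equal-length lists, accessibility followed cell type far more often than genotype. Of 100741 regions, 39559 (39.3%) were present in all 4 libraries and 25129 (24.9%) in both libraries of one cell type alone, 13424 in monocytes and 11705 in CMP/GMP. Both WT libraries alone had 601 regions and both Cxcr3-/- libraries alone 731, together 1332 (1.32%). The crossed pairs, which follow neither factor, had 530 (WT CMP/GMP with Cxcr3-/- monocytes) and 956 (Cxcr3-/- CMP/GMP with WT monocytes), together 1486 (1.48%). Regions that follow genotype were thus not in excess of crossed ones. The larger crossed pair joins the library of each cell type with the higher common pileup per background tag (0.227 against 0.201, and 0.398 against 0.309). Such library differences may raise the crossed count, so this comparison cannot exclude an excess due to genotype. Over 20542 regions with both genotype ratios, Spearman's rho between them was −0.178, or −0.115 after correction for gene density and kind of region. In all, 12 regions were over 1.5-fold higher in Cxcr3-/- in both cell types, 12 over 1.5-fold higher in WT in both, and 109 opposite, where independent ratios would give 22.6, 16.3 and 43.6. The 2 cell-type ratios had a rho of 0.732 over 24337 regions, with 1637 regions beyond 2-fold toward monocytes and 895 toward CMP/GMP in both genotypes and 0 opposite. Within each pair the comparisons use different libraries, so neither pair shares a control. The CMP/GMP genotype ratio had an SD of 0.303 against 0.302 for counting error, while the cell-type ratios spread far beyond it. The genotype rho could therefore hardly show a shared effect, and its contrast with 0.732 does not exclude one.

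**Figure D4:**
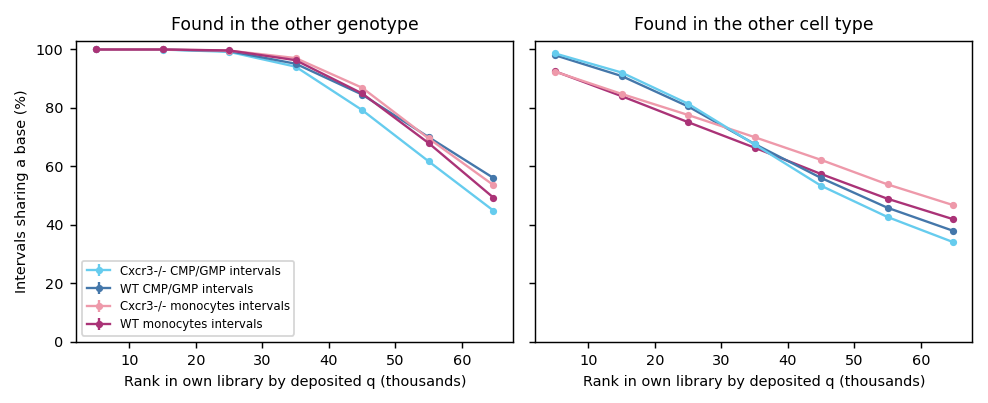
Percent of intervals sharing a base with the other library (y axis) by rank in their own library by the deposited q (x axis), for the other genotype (left) and the other cell type (right), with 95% Clopper-Pearson intervals. In the last bin, from rank 60001 to 69521, 44.8 to 56.0% were found in the other genotype and 34.1 to 46.8% in the other cell type, while the 10000 best were found in full in the other genotype.

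**Figure D5:**
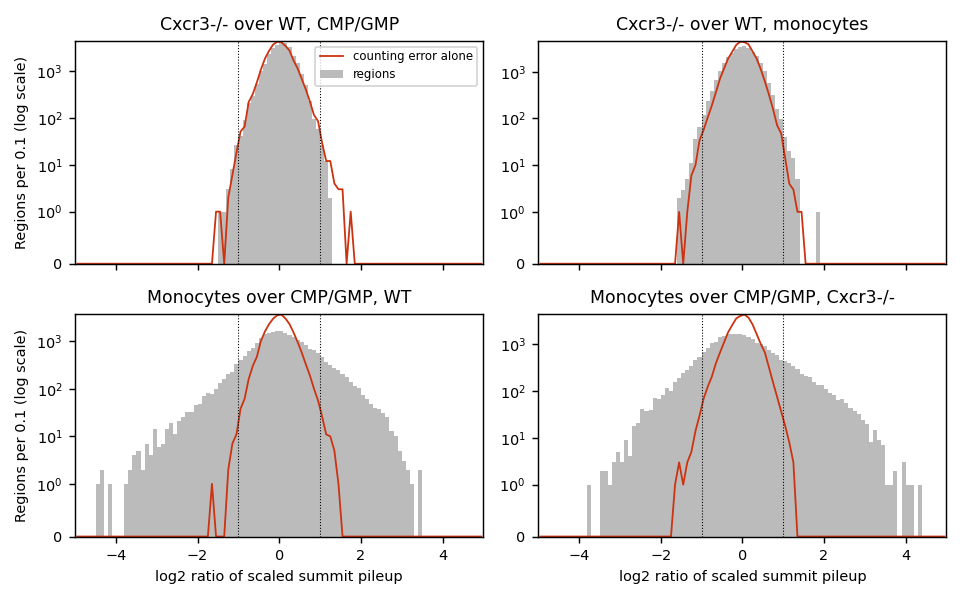
Number of regions per 0.1 of log2 summit pileup ratio (log scale, grey) in each comparison, with the distribution of simulated counting error alone (red line) and 2-fold limits (dotted). The SD was 0.303 and 0.358 for the genotype comparisons in CMP/GMP and monocytes, and 0.784 and 0.855 for the cell-type comparisons in WT and Cxcr3-/-.

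In every library most of the 69521 best intervals lay away from gene ends, with 22.0% at gene ends in WT CMP/GMP, 21.2% in Cxcr3-/- CMP/GMP, 20.3% in WT monocytes and 20.9% in Cxcr3-/- monocytes. Among the 10000 best the shared intervals at gene ends made up 51.7% in Cxcr3-/- and 49.8% in WT CMP/GMP, and 38.9% in Cxcr3-/- and 42.3% in WT monocytes. The 10000 best held no genotype-only interval, so their clustering along the chromosomes or near Cxcr3 could not be examined. Of the 20000 best, 2 intervals were found in Cxcr3-/- CMP/GMP only, those in App and near Lrrc32 described above.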

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

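The tests of an effect alike in both cell types, of sequencing depth, of signal over background and of strong WT-only regions were chosen only after the result was seen, and the pileup ratios themselves were not planned. The Cxcr3-/- to WT ratio went with gene density in opposite directions in the 2 cell types, which is why it is singled out: Spearman's rho across regions was 0.175 in CMP/GMP (0.155 to 0.192 over 200 resamples of 5 Mb windows) and −0.391 in monocytes (−0.420 to −0.358). With 1 library per group, the difference between the cell types was not tested between replicates. The opposite signs are the pattern itself and not a separate test, and with a rho of 0.175 in CMP/GMP they leave out a genotype effect alike in both cell types as the whole cause. In monocytes gene ends differed from other regions by 0.00254, −0.0218 (−0.0389 to −0.00738) and −0.0551 log2 units in the lower, middle and upper tertile of gene density, and rho was −0.424 at gene ends and −0.346 between genes. Gene ends changing as a class are argued against as the whole cause, though a small part at the densest regions stays open. A regional bias of whole libraries, such as base composition, may account for the trend, since it was also present in monocytes more than 10 kb from genes (rho −0.315, −0.349 to −0.277), and a genotype effect that differs between cell types stays open and untested.

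WT monocytes had 98257 intervals and Cxcr3-/- monocytes 78244. Depth is argued against, since background tag density in WT was 0.983 times that in Cxcr3-/-. Strong regions open in WT alone are argued against by the presence comparison, in which 0 of the 10000 best WT intervals lacked a partner among the 69521 best of Cxcr3-/-. The full list contains those, so its 0 adds nothing. Summit pileup at common regions per background tag was 1.29 times higher in WT, so a higher signal over background in that library is a candidate explanation for the longer list. Whether that difference comes from the genotype or from library preparation was not tested.

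Near Cxcr3, flanking DNA of another strain could alter accessibility or mapping. Within 10 Mb of the gene, 3 of 201 regions (1.49%, 0.309 to 4.30%) passed 2-fold in either direction over both cell types, and on the rest of the X chromosome 7 of 915 (0.765%, 0.308 to 1.57%), a ratio of 1.95. Flanking DNA and chance cannot be told apart here, because 3 regions are too few. No biological explanation was tested for this pattern.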

How the results depend on the processing

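The scaling by background tags, the mean pileup limits of 30 and 60 tags and the matching on gene density were chosen only after the result was seen. No paired analysis was possible because each group has 1 library and the labels call every one replicate 1. Motifs were not run, with either window or outside promoters, because they need a genome sequence. In each paragraph the cause was not tested unless given. With autosomes alone, every count and share of the 4 comparisons and of the presence patterns stayed near its main value.

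With all deposited intervals, the shared part of Cxcr3-/- intervals went from 83.0 to 75.8% in CMP/GMP and from 86.9 to 93.2% in monocytes, and the shared part of monocyte intervals from 66.8 to 55.8% in WT and from 69.8 to 70.8% in Cxcr3-/-. WT CMP/GMP-only intervals went from 197 to 96 and crossed regions from 1486 to 3232. In WT monocytes against CMP/GMP 4 lists reversed in their number of intervals: stem and progenitor from −50 to 37, granulocyte from −24 to 10, B cell from −16 to 5 and T and NK cell from −18 to 13. The full lists have 98257 and 69521 intervals, so the monocyte list is then the longer one. Of the other list values, 73 were alike, 3 passed into and 4 out of the outer 5% of random lists. With 50 kb around genes, 78 were alike, 4 passed into and 2 out of it, the latter being the T and NK cell list in the 2 cell-type comparisons.

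With a reciprocal overlap of 50%, Cxcr3-/- and WT-only intervals numbered 460 and 498 in CMP/GMP (73.3% shared) and 158 and 159 in monocytes (79.1% shared). Monocyte-only and CMP/GMP-only intervals numbered 1691 and 669 in WT (55.4% shared) and 1334 and 731 in Cxcr3-/- (57.3% shared). Regions that follow genotype numbered 3038 and crossed regions 4100. A stricter overlap makes more intervals count as unshared by its construction. With summits within 250 bp, Cxcr3-/- and WT-only intervals numbered 111 and 159 in CMP/GMP (82.0% shared) and 110 and 115 in monocytes (84.2% shared), and CMP/GMP-only intervals 447 in WT (64.9% of monocyte intervals shared) and 380 in Cxcr3-/- (65.7% shared).

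At a −log10 q of at least 5, 84.0% of Cxcr3-/- intervals were shared in CMP/GMP, 87.5% in monocytes, and 69.2% of Cxcr3-/- monocyte intervals with CMP/GMP. Ranked by fold enrichment, these shares were 82.5, 86.2 and 69.4%, with 1306 WT monocyte-only and 281 Cxcr3-/- CMP/GMP-only intervals. From the 5000 best, monocyte-only and CMP/GMP-only intervals numbered 241 and 35 in WT and 282 and 23 in Cxcr3-/-. From the 20000 best they numbered 2346 and 1106 in WT and 2280 and 926 in Cxcr3-/-, and 2 intervals were found in Cxcr3-/- CMP/GMP and not in WT. A smaller or larger number of best intervals changes these counts by construction. With intervals under 2000 bp, 2 WT CMP/GMP intervals lacked a partner in Cxcr3-/-.

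At a mean pileup of at least 30 tags, regions that follow genotype went from 1332 to 41, those that follow cell type from 25129 to 6151 and crossed ones from 1486 to 81, fewer because weak regions are left out. With background scaling, regions more than 2-fold higher in Cxcr3-/- and in WT went from 41 and 40 to 170 and 6 in CMP/GMP, and from 81 and 123 to 3 and 1255 in monocytes. Those more than 2-fold higher in monocytes and in CMP/GMP went from 2767 and 1700 to 13109 and 265 in WT, and from 3232 and 2885 to 6040 and 1144 in Cxcr3-/-. At a mean pileup of at least 60 tags the same counts were 0 and 0, 7 and 8, 582 and 270, and 774 and 728, from fewer regions. Background scaling adds 1 constant to all ratios of a comparison, so it cannot move list medians relative to all genes and says nothing about them. Matched on gene density, 75 of 80 list medians were alike, 1 passed into and 4 out of it. What depth limits was not tested by varying it. Intervals without a partner in the other genotype had median pileups of 12 to 19 tags, against 23 to 38 for shared ones.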

Other observations

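Some single genes had large values although the median signal of their CMP/GMP or monocyte list did not stand apart. In Cxcr3-/- against WT monocytes, the glycolysis gene Pgk1 stood at 1.14 ± 0.36, on the X chromosome within 10 Mb of Cxcr3, and the interferon regulator gene Irf1 at −0.71 ± 0.36, Bst2 at −0.67 ± 0.34, the cytokine gene Tnf at −0.61 ± 0.38, Spi1, the gene of the myeloid factor PU.1, at −0.56 ± 0.24 and Cd68 at −0.55 ± 0.25. Of the 19 housekeeping genes, 1 was over 1.5-fold higher in Cxcr3-/- in monocytes and 0 in CMP/GMP. In CMP/GMP, Lgals3 stood at 0.71 ± 0.47, Selp at 0.51 ± 0.32, Irf5 at 0.47 ± 0.33, Ank1 at −0.78 ± 0.53 and Cd34 at −0.39 ± 0.28. Of the CXCR3 ligand genes in CMP/GMP, Cxcl9 stood at 0.41 ± 0.50 and Cxcl10 at −0.16 ± 0.41, the latter within the scaling shift. These genes were chosen after their values were seen. Their values are not relative to all genes or to gene density, with which the genotype ratio moved. In monocytes the median log2 ratio over all regions in the bin of highest gene density was −0.23. The ± covers counting error only.

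Regions in both monocyte libraries and 1 CMP/GMP library were more often shared with Cxcr3-/- CMP/GMP (3185) than with WT CMP/GMP (1815). The Cxcr3-/- CMP/GMP library had 194 background tags per 10 kb and the WT library 135. Regions in both CMP/GMP libraries and 1 monocyte library numbered 3157 with WT and 2691 with Cxcr3-/- monocytes. The App interval found in Cxcr3-/- CMP/GMP and not in WT CMP/GMP (chromosome 16, 85148629 to 85148969) overlapped an App interval of WT monocytes (85148615 to 85148999, 153 tags) that was also missing from WT CMP/GMP.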
